A study of Homo sapiens with 36 samples.

How the data were processed

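Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed with antibodies against BRD2, BRD4 and BRD9 in the breast cancer cell lines MDA-MB-231, SUM159 and HCC1806 after 48 h of treatment. Of the 36 samples, 26 had lists of peaks and formed 6 experiments, each with its own table of region values. A further 9 samples were aligned to the ribosomal DNA (rDNA) repeat, of which 8 had values. The 2 input samples had no values of their own in the files. Every group held 1 library, so no difference had a replicate check, no p-value was computed and no count test was possible, even where reads were recovered.

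Bowtie 1.1.2, MACS 1.4.2 and the genome build hg19 (GRCh37) are named, without their settings, per the submitters' processing notes. Peaks were called separately in each library, as the 26 deposited lists show. The peak lists held, as deposited by the authors, a fold enrichment and the −log10 p and −log10 q of each peak. Peaks less than 12.5 kb apart had been joined by the authors into stitched regions, and the deposited tables list the union of the stitched regions of an experiment's libraries, which was checked by repeating the merge. All 22536 listed regions of the first MDA-MB-231 BRD2 table matched a merged region, as did all regions of the other 5 tables. Between 12 and 22 lines per table were empty in the files and stayed out.

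The HCC1806 table was deposited by the authors in RPM (reads scaled to the depth of the library) without background subtraction. Within a tolerance of 0.0051 RPM, just over the rounding of the file, from 99.97% to 100.0% of its values were whole multiples of 1 read in each library, against 31.7% to 49.7% expected by chance at this tolerance. This gave depths of 31.0 to 48.8 M reads. The other 5 tables hold a score deposited by the authors that resembles RPM after subtraction of a scaled input. Some of these scores were below 0, and neither their scaling nor their background is stated, so the tables themselves do not show depth. The rDNA values were deposited by the authors in RPM per bin of 250 bp, and within a tolerance of 0.000051 RPM from 92.35% to 100.0% of them were whole reads, against 0.1% to 0.4% expected by chance, with depths of 9.8 to 43.0 M reads. The rDNA samples share their titles with the BRD2 and BRD4 drug libraries of MDA-MB-231, so for these 2 tables depth is known if title means library: 38.7, 32.0, 37.4 and 40.3 M reads for BRD2 and 36.2, 43.0, 9.8 and 17.3 for BRD4 (DMSO, GSK2801, JQ1 and both). For the other 3 tables depth is unknown.

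Each table gives the class of a region and the genes it was assigned to, with gene names as the authors gave them. A promoter region in these tables lies within 5 kb of a start site, the greatest distance being 4998 bp. For a gene with several promoter regions the one with the highest mean was used. Regions had median widths of 594 to 1174 bp and reached 260591 bp, and a value covers the whole region. Negative values were set to 0, and changes were computed as log2 of (treated value + 1) over (reference value + 1), a pseudocount of 1 in the deposited unit. On this scale the change of a weakly bound region is understated. Genes whose mean over the experiment's libraries lay in the upper 50% were kept, 5897 to 6517 genes per experiment. A gene was counted as lower or higher when its change reached 2-fold, a rule of size and not a test. The departure of a combined treatment was its log2 change minus the sum of the changes with each single treatment. It combines single libraries, so a scale factor in any of them shifts the departure of every gene. Counts of departures were not centred.

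Gene lists of known function, 18 in all, were written before the data were examined, as were the groups, comparisons, rules and most alternatives. They cover MYC and ribosome-biogenesis targets, the RNA polymerase I machinery, ribosomal proteins, cell cycle and E2F targets, G1 cyclins with their kinases and inhibitors, apoptosis, immediate early and ERK pathway targets, NF-kB targets and cytokines, and receptor tyrosine kinases. The others cover YAP/TEAD targets, mesenchymal and TGF-beta genes, breast epithelial markers, bromodomain and chromatin regulators, the integrated and unfolded protein stress response, sterol and lipid synthesis, the interferon response, DNA repair and p53 targets, and genes of other cell types as a silent-promoter control. A list with at least 5 measured members was described by its median log2 change and by the percentile of that median among 10000 random lists of equal size matched on mean value in 10 bins. A list is called outside the random range below percentile 2.5 or above 97.5. By chance about 5% of lists lie outside. Genes that share a region each count as a member, so such a list holds fewer independent values than genes. Only genes above the filter are measured, so measured members of the silent-promoter control carried signal. Where a JQ1 library is treated in a comparison and reference in another, its own error can give a list opposite calls in them. Comparisons with the same reference library share its error, which can give a list the same call in them.

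Genes named in the text follow a fixed rule. A panel of 20 genes was drawn on where a promoter region was listed, though not every panel gene is printed for every comparison. They are MYC, FOSL1, CCND1, CDK6, E2F1, BCL2L1, MCL1, BIRC5, HEXIM1, BRD2, BRD4, BAZ2A, BAZ2B, NCL, POLR1A, UBTF, EGFR, VIM, SERPINE1 and IL6. Further names are the 5 largest falls and 5 largest rises of each combined treatment, and the members of a list outside the random range with the largest change in its direction.

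Peaks of a control library were called retained when at least 1 bp was overlapped by a peak of the treated library (bedtools 2.31.1), and a promoter was called bound when a peak overlapped its region. Shares carry exact binomial 95% intervals. On the rDNA, mean RPM per bin was computed over the first 13 kb (coding part), its 5′ external transcribed spacer (first 3.5 kb), 18S (4 to 5.5 kb), 28S (8 to 12 kb) and the spacer beyond 14 kb, with 95% intervals for ratios from the recovered reads. All intervals cover counting error only.

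The steps were tested on simulated data for the genes of each experiment, with 200 genes changed. Of the genes changed 4-fold, from 98.0% (MDA-MB-231 BRD9) to 100.0% were recovered, and of those changed 2.5-fold, from 72.0% (MDA-MB-231 BRD9) to 99.0%. No unchanged gene was called in any of the 6 experiments. The simulated reads came from the control library's values at a fixed depth, with counting error only. Input subtraction, unequal depth and variation between libraries were left out, so the test does not show how often real libraries give false calls. Of unchanged lists, 2.0% (SUM159) to 6.5% (MDA-MB-231 BRD2 with drugs) lay outside the random range. Alternatives were other pseudocounts, no filter, values centred on their median, a 1.5-fold rule, stricter peaks, other overlap rules, other random lists and other rDNA scalings. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used. No hg19 genome was at hand, so no sequence was examined, and 1 further kind of region list was left out because neither the labels nor the files say how its score was made.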

Results

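BRD2, BRD4 and BRD9 are proteins whose bromodomains read acetylated histones. BRD2 and BRD4 belong to the BET family, which couples acetylated promoters and enhancers to transcription, and BRD9 is a subunit of a non-canonical BAF remodelling complex. The drug JQ1 competes with acetyl-lysine for the bromodomains of BET proteins. GSK2801 binds the bromodomains of BAZ2A and BAZ2B, subunits of imitation-switch remodelling complexes, and that of BRD9. BAZ2A is the core of the nucleolar remodelling complex that silences rDNA repeats. The series title names the question: how triple negative breast cancer cells respond to BAZ2 and BET bromodomain inhibition, alone and combined.

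MDA-MB-231 and SUM159 are mesenchymal-like triple negative lines, and HCC1806 is a basal-like one. MDA-MB-231 was profiled for BRD2, BRD4 and BRD9, and SUM159 for BRD2, after 48 h with DMSO, 10 µM GSK2801, 100 nM JQ1 or both drugs. In a separate experiment MDA-MB-231 received siRNA against BAZ2A, BAZ2B or no gene (non-targeting, NT), each with and without 100 nM JQ1. HCC1806 received BAZ2B or NT siRNA with and without 500 nM JQ1. Each of these 26 groups was a single library, so none of the differences below has a replicate check. The HCC1806 libraries held 41.1 (NT), 34.8 (BAZ2B siRNA), 31.0 (NT + JQ1) and 48.8 (BAZ2B siRNA + JQ1) M reads.

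In DMSO-treated MDA-MB-231 the sites of the 3 proteins overlapped widely. BRD4 peaks overlapped 93.8% (95% interval 93.5 to 94.1) of the 26742 BRD2 peaks and 91.2% (91.0 to 91.5) of the 39937 BRD9 peaks. BRD2 peaks overlapped 45.4% (45.0 to 45.9) of the 50095 BRD4 peaks, and BRD9 peaks overlapped 78.1% (77.6 to 78.6) of the BRD2 peaks. Of the MDA-MB-231 BRD2 peaks, 75.6% were overlapped in SUM159, which had 44040 peaks. Of the 31438 peaks with NT siRNA in MDA-MB-231, 64.1% were overlapped in HCC1806, which had 38283. Promoters made up 10297 of the 22536 regions in the MDA-MB-231 BRD2 drug experiment, and enhancers 7760.

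With JQ1, BRD2 in the drug experiment of MDA-MB-231 fell further at promoters of ribosomal protein genes, MYC targets and cell cycle genes than at matched promoters, and less at immediate early, YAP/TEAD and epithelial genes. In the siRNA experiment with the same dose the ribosomal protein, MYC and epithelial lists lay inside the random range (percentiles 19.6, 3.99 and 17.8), so only the other 3 calls recurred. Relative to DMSO, the ribosomal protein promoters had a median log2 change of -0.79 over 42 genes (percentile 0.0 of matched random lists), with RPS8 at -1.31 and RPS14 at -1.24. The MYC and ribosome-biogenesis targets had a median of -0.69 over 20 genes (percentile 1.24), led by NOP58 (-1.22) and NCL (-1.22), which encode nucleolar proteins. Cell cycle and E2F targets had a median of -0.74 over 16 genes (percentile 0.69), with the replication helicase gene MCM5 at -1.44 and the ribonucleotide reductase gene RRM2 at -1.31. The median of all 6115 genes was -0.45 (SD across genes 0.42), so the ribosomal protein list lay 0.35 below it.

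Immediate early and ERK pathway targets lay above that median, at -0.11 over 20 genes (percentile 99.96). The dual-specificity phosphatase genes DUSP1 and DUSP6, feedback inhibitors of MAP kinases, stood at 0.93 and 0.80, and the stress transcription factor gene ATF3 at 0.69. YAP/TEAD targets had a median of 0.03 over 15 genes (percentile 100.0), with CTGF at 1.5 and CYR61 at 0.40, both genes of secreted matricellular proteins. Breast epithelial markers had a median of 0.10 over 5 genes (percentile 99.2, and 95.87 with the mean over members), with KRT8 at 0.12 and KRT18 at 0.10. In all, 461 genes were at least 2-fold lower and 3 higher, and 74 were lower and 67 higher once the median was set to 0.

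The transcription factor gene MYC, a common readout of BET inhibition, did not lose BRD2 in the drug experiment of MDA-MB-231. Its promoter region (hg19 chromosome 8, 128746300 to 128755639) had scores of 26.6 with DMSO, 34.7 with GSK2801, 37.4 with JQ1 and 39.9 with both, a log2 change of 0.48 with JQ1. NCL (chromosome 2, 232317678 to 232330307) went from 14.1 to 5.49 with JQ1 and 3.46 with both drugs. The survivin gene BIRC5 changed by -1.26 with JQ1 and -2.37 with both, from a score of 8.53. HEXIM1, which encodes an inhibitor of P-TEFb, changed by -0.47 and -0.80, VIM by -0.59 and -1.16, CDK6 by -0.34 and -0.79, and BRD2 by -0.51 and -0.57. The AP-1 gene FOSL1 stood at 0.14 and -0.11, MCL1 at -0.14 and -0.41, and SERPINE1 at -0.09 and -0.25. Changes of CCND1, EGFR, BCL2L1, UBTF, E2F1, POLR1A and BAZ2B with JQ1 ran from -0.80 to -0.22, and BAZ2A stood at 0.01. IL6 lay below the low-value filter.

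GSK2801 by itself moved BRD2 little. The median change was 0.15, and no gene was 2-fold lower or higher. Immediate early and ERK pathway targets lay high (median 0.27, percentile 99.72, 17 of 20 above the median of all genes), with DUSP1 at 0.58, IER2 at 0.44 and FOSL2 at 0.43. Ribosomal proteins (0.08, percentile 0.13) and cell cycle targets (0.04, percentile 0.69) lay low, with RPS8 at -0.26 and MCM5 at -0.16. The comparisons with GSK2801, JQ1 and both drugs share 1 DMSO library. Error in that library can give a list the same call in each of them, so these calls are not independent.

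Against DMSO, the combination lowered BRD2 furthest at cell cycle promoters. Their median was -1.38 (percentile 0.0), and 14 of 16 genes were at least 2-fold lower, among them RRM2 (-2.22), the thymidylate synthase gene TYMS (-1.79), E2F3 (-1.73) and MCM5 (-1.69). The list of immediate early and ERK pathway targets had a median of -0.25 (percentile 99.99), with DUSP1 at 0.92 and DUSP6 at 0.80. YAP/TEAD targets stood at -0.38 (percentile 99.95) and epithelial markers at -0.09 (percentile 99.7), with KRT18 at 0.20. Apoptosis genes had a median of -0.70 over 17 genes (percentile 82.82) and receptor tyrosine kinases -0.58 over 6 (89.95). Bromodomain and chromatin regulators stood at -0.78 over 18 genes (65.24) and sterol and lipid synthesis at -0.89 over 8 (36.35), all 4 within the random range.

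The largest falls with the combination were in regions of CDH13, which encodes T-cadherin, AKR1E2, the transglutaminase gene TGM2, the prefoldin gene PFDN1 and the ubiquitin ligase gene HERC4. These regions were 19859 (AKR1E2) to 31601 bp (PFDN1) wide, so their values reach beyond the promoters. The CDH13 region (chromosome 16, 82662975 to 82689215) went from 28.4 to -0.82, a log2 change of -4.88 that the pseudocount bounds because the treated score was below 0. AKR1E2 changed by -4.53, TGM2 by -4.03 and PFDN1 by -3.78, bounded in the same way, and HERC4 by -3.69. CTGF (chromosome 6, 132268260 to 132276075) rose from 9.30 to 33.3, a log2 change of 1.74. ARHGEF3, an exchange factor gene for RhoA, changed by 1.64, the helix-loop-helix inhibitor gene ID1 by 1.16, the Slit receptor gene ROBO1 by 1.04 and ZNF878 by 1.03. The median over all genes was -0.83 (SD across genes 0.51), with 2105 genes lower and 7 higher, or 187 and 151 relative to the median.

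Adding GSK2801 to JQ1 also came with lower BRD2 at cell cycle promoters than at matched promoters. Against JQ1 by itself the cell cycle list had a median of -0.61 (percentile 0.02), with RRM2 at -0.91 and E2F1 at -0.81, while all genes had a median of -0.37. Ribosomal proteins (-0.26, percentile 99.88), the RNA polymerase I machinery (-0.23 over 12 genes, percentile 98.71) and stress response genes (-0.24 over 17, percentile 98.54) changed less than matched lists. POLR1C stood at 0.21, POLR1A at 0.10 and the chaperone gene DNAJB1 at 0.07. Ribosomal proteins had been called low with the same JQ1 library against DMSO, so error in that library can give both calls. ERK pathway and immediate early targets had a median of -0.15 (percentile 99.99), with JUN at 0.19. The combination lay below the sum of both single treatments, with a median departure of -0.53 (SD across genes 0.27). In these values 269 genes lay at least 2-fold below the sum and 1 above it. The counts were not centred, and a scale factor of a single library would shift every gene. The DMSO and NT siRNA control libraries of MDA-MB-231 alone differed by a median of 0.29. For BRD2 the low cell cycle call against JQ1 did not recur in other experiments. In SUM159 the list lay inside the random range. In the siRNA experiment, against NT siRNA with JQ1, it lay high with BAZ2A siRNA and JQ1. With BAZ2B siRNA and JQ1 it lay inside, and high with the mean over members (97.67).

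Promoters kept more of their BRD2 than enhancers did in these cells. With JQ1, 8236 promoter regions had a median change of -0.34 and 2001 enhancer regions -0.68. Of the DMSO peaks, 90.1% were retained with GSK2801, 68.6% (68.0 to 69.2) with JQ1 and 54.2% (53.6 to 54.8) with both. The libraries held 32010, 24053 and 18284 peaks, and with equal numbers of the strongest peaks the shares were 86.6%, 75.4% and 70.2%. With the combination 1041 promoter calls were lost and 211 gained, against 444 lost and 376 gained with JQ1 and 99 and 455 with GSK2801.

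**Figure D1:**
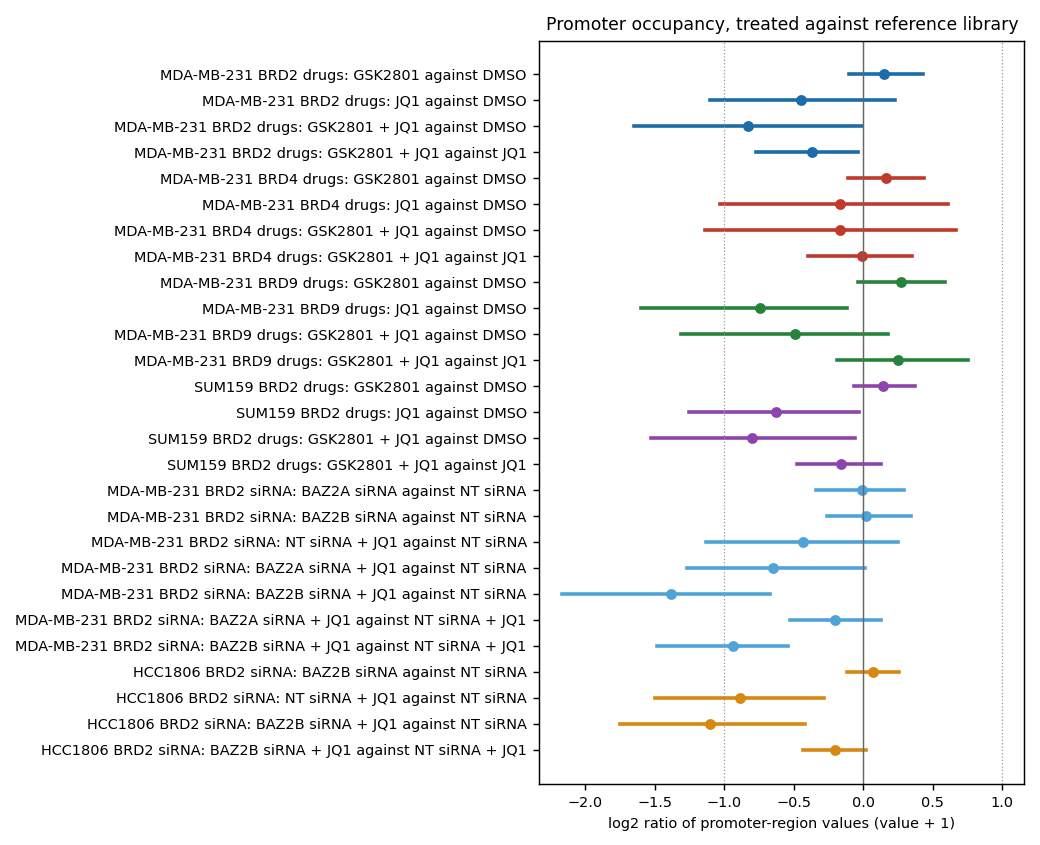
Log2 ratio of promoter-region values (value + 1) for each comparison, on the horizontal axis. Points are medians over genes, bars run from the 5th to the 95th percentile of genes, and dotted lines mark 2-fold. The medians run from -1.38 (BAZ2B siRNA + JQ1, MDA-MB-231) to 0.27 (BRD9 with GSK2801).

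With JQ1, BRD4 in MDA-MB-231 fell at ribosomal genes without a broad fall. The library titled JQ1 carries GSK2801 in its treatment label, and was grouped by its title, which its rDNA counterpart shares. MYC and ribosome-biogenesis targets had a median of -0.54 over 22 genes (percentile 0.16, and 2.72 with the mean over members), led by NCL (-0.99) and the pyrimidine synthesis gene CAD (-0.97). Ribosomal proteins stood at -0.49 (percentile 0.08), with RPS23 at -1.31 and RPL11 at -1.21. Immediate early and ERK pathway targets had a median of 0.12 over 21 genes (percentile 99.2), with DUSP6 at 1.30 and FOS at 0.76. The median of all 6516 genes was -0.17, with 351 lower and 79 higher, or 210 and 143 relative to the median. GSK2801 by itself gave a median of 0.16, 0 genes lower and 1 higher, and placed sterol and lipid synthesis genes low (-0.04 over 10, percentile 0.04), with IDI1 at -0.19.

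With both drugs against DMSO, BRD4 fell further at cell cycle promoters than at matched promoters. Cell cycle targets had a median of -0.53 over 15 genes (percentile 1.88), with RRM2 at -1.69, TYMS at -1.54 and E2F3 at -1.26. DUSP6 reached 1.56, FOS 1.15 and EGR1 0.88, in a list with a median of 0.12 (percentile 98.8, and 96.76 against width-matched lists). MYC and ribosome-biogenesis targets stood at -0.49 (percentile 0.96, but 12.96 with the mean), with NOP58 at -1.16 and WDR43 at -1.05. Genes of other cell types, a list meant as a silent-promoter control, stood at -0.91 over 5 measured members (percentile 0.58), with INS at -1.78 and MBP at -0.93. These members carried BRD4, with DMSO scores from 7.04 (CD14) to 35.99 (CD79A), so the list could not serve as a silent control. It lay further out than the cell cycle list, so a low percentile by itself does not set cell cycle genes apart here. Interferon response genes stood at -0.08 over 5 (65.27) and DNA repair and p53 targets at -0.26 over 9 (31.31).

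TM4SF18, a tetraspanin-like gene, changed by -3.92 in BRD4 with both drugs, the ciliary gene TTC8 by -3.08, AKR1E2 by -2.95, CDH13 by -2.81 and ADAMTSL1 by -2.78. Their regions were 8473 (TTC8) to 43325 bp (ADAMTSL1) wide. One region holding SLC9A3R1 and RAB37 rose by 2.49, the homeobox gene LHX6 by 2.47, the metallothionein gene MT1X by 2.29 and CTGF by 2.27, from a score of 26.8 to 133. MYC stood at 0.35 with JQ1 and 0.74 with both (64.4 to 82.3 and 108), and UBTF at 0.23 and 0.41. NCL stood at -0.82 with both, VIM at -0.65 and IL6 at -0.66. The remaining panel genes that passed the filter ran from -0.72 (POLR1A) to 0.27 (BAZ2A).

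Against JQ1, BRD4 with both drugs lay high at ribosomal protein genes (median 0.15, percentile 100.0, RPL11 0.65). MYC and ribosome-biogenesis targets lay high too (0.13, percentile 99.31, and 94.06 with the mean), with NOP16 at 0.57 and MYC at 0.39. Of all genes in this comparison, 3 were 2-fold lower and 0 higher. Both lists had been called low with the same JQ1 library against DMSO, so error in that library can give both calls. Cell cycle targets (-0.14, percentile 1.90, and 3.09 against unmatched lists, RRM2 -0.71) and genes of other cell types (-0.34, percentile 0.27) lay low. With both drugs 460 genes were lower and 95 higher (286 and 178 relative to the median of -0.17), and the median departure from the sum was -0.17. Of the DMSO peaks 91.5% were retained with GSK2801, 64.5% with JQ1 and 76.2% with both, from lists of 56601, 43364 and 57660 peaks. The rDNA samples of the same titles had depths of 36.2 (DMSO), 43.0, 9.8 and 17.3 M reads, an order that the shares follow, so depth is not excluded as the source of their differences. With equal numbers of the strongest peaks the gap between JQ1 and both drugs nearly closed, at 70.6% and 71.7%. With JQ1 782 promoter calls were lost and 221 gained, and with both drugs 274 and 490. The net gain with both drugs turned into a net loss with strict peaks, 1357 lost and 652 gained, against 3454 and 161 with JQ1.

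BRD9, which is not a BET protein, had lower values with JQ1 at most promoters in MDA-MB-231, and lower at cell cycle genes than at matched promoters. The DMSO library of BRD9, the reference for these values, carries “DMSO 48h rDNA” as its treatment label, and the names of BRD9 peaks carry “R2”, which the labels do not explain. All 4 libraries were taken as 1 BRD9 experiment. Cell cycle targets had a median of -1.21 over 14 genes (percentile 0.19), 10 of them at least 2-fold lower, with CDK2 at -1.85, RRM2 at -1.84 and the Aurora kinase gene AURKB at -1.43. YAP/TEAD targets lay high at -0.61 over 16 genes (percentile 97.63, but 87.17 against unmatched and 96.91 against width-matched lists), with CTGF at 0.42. Of the panel, E2F1 changed by -1.33, VIM by -1.12, IL6 by -1.02, SERPINE1 by -0.99, UBTF by -0.98, NCL by -0.92, FOSL1 by -0.74 and MYC by -0.27. The remaining panel genes above the filter ran from -0.86 (BCL2L1) to -0.38 (EGFR). The median of all 5897 genes was -0.74, with 1553 lower and 18 higher, or 222 and 91 relative to the median. Of these genes 96.7% had a change below 0, and promoter and enhancer regions had medians of -0.59 and -0.63. A weaker JQ1 library and a real loss of BRD9 at all regions both give such a broad fall. With 1 library per group and unknown depth they cannot be told apart.

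With GSK2801, whose targets include BRD9, BRD9 values showed no broad fall at promoters. The median was 0.27 with 0 genes lower and 11 higher, or 0 and 1 relative to the median. Depth and scaling of these libraries are unknown, so a scale factor of the GSK2801 library could hide a loss of BRD9. Mesenchymal and TGF-beta genes (0.12 over 14, percentile 0.18, COL1A1 -0.07) and epithelial markers (0.05 over 7, percentile 0.28, and 3.79 with the mean) lay low. Among the epithelial markers KRT8 and KRT18 share 1 region, so the list holds fewer independent values than genes. Both drugs together gave a smaller fall than JQ1, with a median of -0.49, 715 genes lower and 30 higher, or 181 and 115 relative to the median. Cell cycle targets stood at -0.82 (percentile 0.93), with RRM2 at -1.62 and CDC6 at -1.33. FEZ2 changed by -3.93 with both drugs, the methyltransferase-like gene PRDM8 by -3.38, CDH13 by -3.37 and TM4SF18 by -3.04. PAPL changed by -3.12, which the pseudocount bounds because its treated score was below 0. The regions of these falls were 18727 (TM4SF18) to 41710 bp (FEZ2) wide. The proteoglycan gene EPYC changed by 2.51, GFOD1 by 2.36, the zinc finger genes ZNF433 and ZNF799 by 1.58 and 1.57, and MAL2 by 1.52.

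Against JQ1, both drugs gave BRD9 a median of 0.25, with 0 genes lower and 115 higher, or 15 and 36 relative to the median. UBTF, which encodes the rDNA transcription factor UBF, stood at 0.72, BAZ2A at 0.65 and E2F1 at 0.55. YAP/TEAD targets lay low at 0.12 (percentile 2.19, and 4.04 against unmatched lists). YAP/TEAD targets had been called high with the same JQ1 library against DMSO, so error in that library can give both calls. The median departure from the sum was -0.01, with 20 genes below and 33 above. The number of BRD9 peaks went from 39937 with DMSO to 51657 with GSK2801, 19828 with JQ1 and 31362 with both, and 40.9% (40.4 to 41.4) of the DMSO peaks were retained with JQ1 against 57.7% (57.2 to 58.2) with both. With equal numbers of the strongest peaks these shares were 60.8% and 61.0%, so the difference was not kept. JQ1 lost 3680 promoter calls and both drugs 2163.

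In SUM159, JQ1 lowered BRD2 at cytokine and ribosomal protein genes. NF-kB targets and cytokines had a median of -1.05 over 8 genes (percentile 0.20), with the chemokine genes CXCL8 at -2.63, CXCL2 at -1.52 and CCL20 at -1.19, and TNFAIP2 at -1.47. Ribosomal proteins stood at -0.99 over 41 genes (percentile 0.0), with RPS12 at -1.56. YAP/TEAD targets had a median of -0.34 over 14 genes (percentile 99.58), with CTGF at 0.10 and LATS2 at 0.09. Receptor tyrosine kinases stood at -0.29 over 8 (percentile 98.45, and 90.24 with the mean), with MET at -0.09 and AXL at -0.19. The list of immediate early and ERK pathway targets stood at -0.47 over 20 (percentile 97.71, and 95.62 against width-matched lists). The median of all 6517 genes was -0.63, with 1009 lower and 2 higher, or 87 and 53 relative to the median.

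MYC in SUM159 had a BRD2 score of 301 with DMSO, 392.4 with GSK2801, 373.0 with JQ1 and 374 with both, a log2 change of 0.31 with JQ1 and with both. SERPINE1, the plasminogen activator inhibitor gene, changed by -1.28 and -1.56, NCL by -1.15 and -1.10, IL6 by -0.91 and -0.99, POLR1A by -0.83 and -0.92, and FOSL1 by -0.66 and -0.77. The remaining panel genes above the filter ran from -0.89 (E2F1) to -0.11 (MCL1) with both drugs. The BRD4 promoter had a region in SUM159 only, with a score of 0.34.

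The largest falls with both drugs in SUM159 took BRD2 scores below 1. One region holding the chemokine receptor gene CCR7 and the tensin gene TNS4 (chromosome 17, 38632287 to 38717007) went from 93.7 to 0.42, a log2 change of -6.06. The Wnt antagonist gene SOST and the aromatase gene CYP19A1 both changed by -5.42, and SYT8 by -4.98, all 3 with treated scores below 0 (the first 2 also with JQ1 by itself) and so bounded by the pseudocount. The regions of these falls were 20731 (SYT8) to 84721 bp (CCR7 and TNS4) wide, so their values reach beyond the promoters. IGFL1 rose by 3.49, from 1.30 to 24.9, the steroid-metabolizing gene AKR1C3 by 1.69, a region of the thioredoxin reductase gene TXNRD1 and EID3 by 1.22, and the hyaluronidase gene TMEM2 by 1.08. Mesenchymal and TGF-beta genes lay high at -0.47 over 14 (percentile 99.37, and 89.16 with the mean), with SNAI2 at 0.33. Ribosomal proteins stood at -1.05 (percentile 0.03) with 22 of 41 at least 2-fold lower, and YAP/TEAD targets at -0.42 (percentile 99.85, CTGF 0.39). ERK pathway and immediate early targets stood at -0.54 (percentile 99.33), with ATF3 at 0.26. The median was -0.80, with 2054 genes lower and 5 higher, or 140 and 126 relative to the median.

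Against JQ1, both drugs had a median of -0.16 in SUM159, with 10 genes lower and 0 higher. Ribosomal proteins (-0.09, percentile 99.34, RPLP1 0.34), MYC and ribosome-biogenesis targets (-0.07, percentile 98.35, and 97.45 against width-matched lists, ODC1 0.16) and immediate early and ERK pathway targets (-0.04, percentile 99.69, ATF3 0.49) changed less than matched lists. Ribosomal proteins had been called low with the same JQ1 library against DMSO, so error in that library can give both calls. The median departure from the sum was -0.30, with 23 genes 2-fold below it (not centred). GSK2801 by itself had a median of 0.14, 0 genes lower and 1 higher, with cell cycle targets low at 0.06 (percentile 0.52, and 11.58 with the mean). Retention of the DMSO peaks was 90.1% with GSK2801, 51.7% (51.2 to 52.1) with JQ1 and 53.9% (53.4 to 54.4) with both, from lists of 58096, 28485 and 32422 peaks. The order of JQ1 and both drugs turned with 50% of the peak overlapped (37.0% and 36.7%), among strict peaks (83.9% and 83.5%) and with equal numbers of the strongest peaks (69.9% and 67.1%), so it is left open. Promoter and enhancer regions both had a median change of -0.55 with JQ1, and -0.63 and -0.78 with no pseudocount. JQ1 lost 698 promoter calls and gained 85, and both drugs lost 659 and gained 176.

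**Figure D2:**
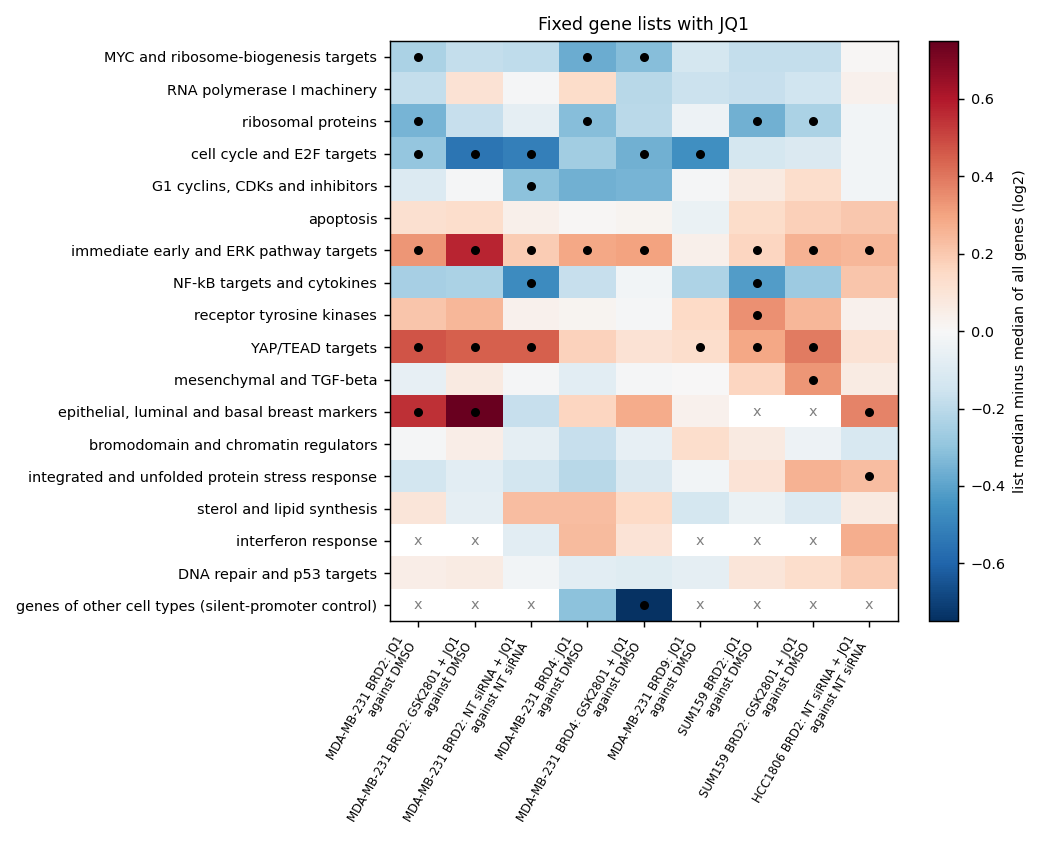
Median log2 change of each gene list minus the median of all genes, as colour, for 9 comparisons with JQ1. Dots mark lists outside the central 95% of matched random lists, and crosses mark lists with fewer than 5 measured members. Immediate early and ERK pathway targets are above 0 in each column, by 0.57 with both drugs in MDA-MB-231 BRD2.

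BAZ2A and BAZ2B, both bound by GSK2801, were targeted by siRNA in MDA-MB-231. ChIP-seq does not measure the knockdown, and the BRD2 score at the BAZ2B promoter (9.41 with NT, 10.8 with BAZ2B siRNA) checks nothing. With BAZ2A siRNA, BRD2 lay high at cell cycle promoters (median 0.21 over 15 genes, percentile 99.99), with CCNE2 at 0.58 and RRM2 at 0.50, and MYC stood at -0.60. With BAZ2B siRNA, cell cycle targets (0.14, percentile 97.94, CDK1 0.80) and YAP/TEAD targets (0.14, percentile 98.99, ANKRD1 0.46) lay high, neither of them with the mean over members (97.25 and 79.14). Both comparisons share 1 NT siRNA library, so error in it can give the cell cycle list a high call in both. Among 6254 genes the medians were -0.01 and 0.02, with 2 lower and 0 higher for BAZ2A and 0 and 1 for BAZ2B.

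With NT siRNA, JQ1 lowered BRD2 at cell cycle and cytokine genes. Cell cycle targets had a median of -0.94 (percentile 0.0), with RRM2 at -1.80, E2F3 at -1.37 and CDC25A at -1.31. NF-kB targets and cytokines stood at -0.90 over 8 (percentile 0.30), with CSF2 at -2.28 and CXCL2 at -1.14. G1 cyclins, CDKs and inhibitors stood at -0.75 over 10 (percentile 0.97, and 8.35 with the mean), with CDKN1C at -1.08. YAP/TEAD targets had a median of 0.02 (percentile 99.97), with CTGF at 1.44 and CYR61 at 0.55, and immediate early and ERK pathway targets -0.24 (98.01, and 95.3 against width-matched lists). The median was -0.43, with 528 genes lower and 13 higher, or 106 and 72 relative to the median. MYC stood at 0.30, MCL1 at 0.27, FOSL1 at 0.12, NCL at -1.12, IL6 at -0.81 and CDK6 at -0.77. The remaining panel genes above the filter ran from -0.61 (EGFR) to 0.08 (BAZ2A).

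The JQ1 changes of single genes correlated between the drug and the siRNA experiments of MDA-MB-231, which have separate libraries, while the list calls agreed in part. Cell cycle, immediate early and YAP/TEAD lists were called in both, though the immediate early call with NT siRNA was lost against width-matched (95.3) and unmatched lists (96.85). Ribosomal proteins (median -0.50), MYC and ribosome-biogenesis targets (-0.62) and epithelial markers (-0.61) lay inside the range with NT siRNA, so these 3 calls of the drug experiment were not reproduced. The NF-kB and G1 lists, called with NT siRNA (G1 not with the mean, 8.35), stood at -0.70 over 5 genes (percentile 15.5) and -0.55 over 10 (28.34) in the drug experiment, inside the range, and the difference was not tested. Over 5633 genes the log2 changes correlated with Pearson's r of 0.80 and Spearman's rho of 0.78, and 89.95% had the same sign. This is a correlation across genes, which are not independent replicates. Of 427 and 445 genes at least 2-fold lower, 251 were lower in both, against 33.7 for independent lists. The control libraries themselves differed by a median of 0.29 over 4239 genes with matching regions (SD 0.26), 1 of them 2-fold lower and 16 higher with NT siRNA.

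Against NT siRNA without JQ1, BAZ2A siRNA with JQ1 gave lower BRD2 at cytokine genes, much as JQ1 with NT siRNA did. NF-kB targets stood at -1.01 (percentile 0.75), and at -0.16 (69.53) against NT siRNA with JQ1, with CSF2 at -2.43, TNFAIP2 at -1.39 and IL6 at -1.07. YAP/TEAD targets fell less than matched lists, at -0.13 (percentile 99.99, CTGF 0.46), but lay below their 0.02 with NT siRNA and JQ1 (CTGF 1.44), and immediate early and ERK pathway targets stood at -0.30 (99.96, DUSP6 0.49). The Ras exchange factor gene RASGRF1 changed by -4.17, CDH13 by -3.86, the cytokine gene IL24 by -3.09 and a region of KRTAP2-1 and KRTAP2-3 by -3.01. Their regions were 18275 (KRTAP2-1 and KRTAP2-3) to 28454 bp (CDH13) wide. The poly(A) polymerase gene FAM46C changed by 2.53, ARHGEF3 by 1.73, a region of ZNF491 and ZNF440 by 1.15 and TLR4 by 1.09. The median was -0.65, with 1008 genes lower and 5 higher, or 79 and 70 relative to the median. Against NT siRNA with JQ1 the median was -0.20, and cell cycle targets lay high (-0.02, percentile 99.86, CDK1 1.13, RRM2 0.54), as did DNA repair and p53 targets (-0.07 over 10, 97.86, and 91.33 with the mean), with CHEK1 at 0.11. Cell cycle targets had been called low with NT siRNA and JQ1, the reference here, so error in that library can give both calls. The median departure from the sum was -0.19.

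BAZ2B siRNA with JQ1 gave lower BRD2 values than NT siRNA with JQ1 at 99.9% of promoters. The other values of this paragraph are against NT siRNA without JQ1, where 5109 of all 6254 genes were at least 2-fold lower. On that reference all 8 measured NF-kB targets were at least 2-fold lower (median -1.87, percentile 0.37), with CXCL2 at -2.13 and CSF2 at -4.00 (bounded by the pseudocount, as its treated score was below 0), as were all 15 cell cycle targets (median -1.84, 0.08), with RRM2 at -2.26 and E2F3 at -2.18. YAP/TEAD targets stood at -0.86 (percentile 100.0, CTGF 0.30) and immediate early and ERK pathway targets at -1.12 (99.41, DUSP6 -0.37). The Bardet-Biedl gene BBS10 changed by -6.13, TGM2 by -5.37, CDH13 by -5.20 and a region of HERC4 and MYPN by -4.58, and all 4 treated scores were below 0, so the pseudocount bounds these changes too. Their regions were 28454 (CDH13) to 90467 bp (BBS10) wide, so the values reach beyond the promoters. FAM46C changed by 2.07, ARHGEF3 by 0.87, a region of PMF1 and PMF1-BGLAP by 0.53 and TLR4 by 0.51. MYC stood at -0.69, FOSL1 at -0.74, MCL1 at -0.65 and NCL at -1.99. All 3 of MYC, FOSL1 and MCL1 lie above 0 once the median is set to 0. The median was -1.38, with 5109 genes lower and 1 higher, but 189 and 97 relative to the median.

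Against NT siRNA with JQ1, BAZ2B siRNA with JQ1 had a median of -0.94, with 2521 of 6254 genes lower and 0 higher, or 66 and 4 relative to the median. No gene list lay outside the random range in this comparison, and 4 of the 8 NF-kB targets were at least 2-fold lower (median -1.04, percentile 20.54). The median departure from the sum was -0.96, with 2811 genes 2-fold below it. This count was not centred and so holds any library-wide shift. Retention of the NT siRNA peaks was 79.5% with BAZ2A siRNA, 85.6% with BAZ2B siRNA, 68.8% with NT + JQ1, 54.0% with BAZ2A siRNA + JQ1 and 35.6% (35.1 to 36.1) with BAZ2B siRNA + JQ1. The last 3 lists held 29970, 19793 and 13070 peaks, and with equal numbers of the strongest peaks their shares were 77.7%, 78.3% and 73.5%, which turns the order of the first 2. BAZ2B siRNA + JQ1 lost 2396 promoter calls and gained 24. Promoter regions had a median of -0.34 and enhancer regions -0.77 with NT siRNA and JQ1.

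In HCC1806, 500 nM JQ1 with NT siRNA lowered BRD2 less at epithelial and immediate early genes than at matched promoters. Epithelial markers had a median of -0.52 over 14 genes (percentile 99.98), with the E-cadherin gene CDH1 at -0.08 and KRT18 at -0.18. The list of immediate early and ERK pathway targets stood at -0.65 over 20 (percentile 99.38, and 94.73 against width-matched lists), with EGR1 at 0.89 and ATF3 at 0.07. Stress response genes stood at -0.67 over 16 (98.28, and 94.67 against width-matched lists), with DNAJB1 at -0.12. In this list HSPA1A and HSPA1B share 1 region. CCND1 changed by -1.22, from 71.3 to 29.99 RPM, NCL by -1.19, BRD2 by -1.14, BCL2L1 by -1.11, BIRC5 by -1.06 and EGFR by -1.06. MYC changed by -0.55 (61.2 to 41.5 RPM) and MCL1 by -0.08. The remaining panel genes above the filter ran from -1.01 (UBTF) to -0.49 (BAZ2B). The median of all 6513 genes was -0.89, with 2478 lower and 1 higher, or 54 and 60 relative to the median.

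Against NT siRNA without JQ1, BAZ2B siRNA with JQ1 gave low BRD2 in HCC1806 at chromatin regulator promoters. Their median was -1.39 over 17 genes (percentile 0.56), and 14 were at least 2-fold lower, as were 3880 of all 6513 genes. The acetyltransferase gene CREBBP stood at -1.91, BRD1 at -1.88 and BRD9 at -1.73. JQ1 with NT siRNA gave most of this, with a list median of -1.01 (percentile 13.27) and CREBBP at -1.59, BRD1 at -1.80 and BRD9 at -1.46. Adding BAZ2B siRNA to JQ1 moved these genes by -0.32, -0.08 and -0.28, and the list by -0.28 (percentile 2.69, inside the range, but 2.22 and outside it with the mean). Epithelial markers (-0.76, percentile 99.7, CDH1 -0.14) and immediate early and ERK pathway targets (-0.83, percentile 98.99, and 90.59 against width-matched lists) lay high. The transporter gene SLC12A8 changed by -3.07 (17.6 to 1.21 RPM), the acyltransferase gene AGPAT3 by -2.79, CASD1 by -2.75, KIAA1614 by -2.72 and the parvin gene PARVB by -2.70. EGR1 stood at 0.73, the Wnt co-receptor gene LRP6 at 0.58 and a histone cluster region with HIST1H3F, HIST1H3D and HIST1H2BG at 0.41. MYC stood at -1.02 and HEXIM1 at -1.03, both above 0 once the median is set to 0. The median was -1.10, with 3880 genes lower and 0 higher, or 71 and 66 relative to the median.

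BAZ2B siRNA by itself had a median of 0.07 in HCC1806 with no gene 2-fold changed, and stress response genes low at 0.01 (percentile 1.35, and 4.60 with the mean). Against NT siRNA with JQ1, adding BAZ2B siRNA gave a median of -0.20, with 1 gene lower and 0 higher. NF-kB targets lay high (-0.10 over 10, percentile 97.62, and 92.45 with the mean) and epithelial markers low (-0.28, 1.19, and 3.48 with the mean), with XBP1 at -0.52. In the NF-kB list IL1A and IL1B share 1 region, so it holds fewer independent values than genes. Epithelial markers had been called high with NT siRNA and JQ1, the reference here, so error in that library can give both calls. The median departure from the sum was -0.28. In the deposited values promoter regions changed more than enhancer regions with JQ1, by -0.88 against -0.63, while the peaks went the other way, with 64.3% of promoter peaks and 27.1% of enhancer peaks retained (36.8% and 29.3% among peaks of matched strength). Retention of NT siRNA peaks was 83.2% with BAZ2B siRNA, 45.7% (45.2 to 46.2) with JQ1 and 42.9% (42.5 to 43.5) with both (72.9% and 71.1% for the last 2 with equal numbers of the strongest peaks), and JQ1 lost 1096 promoter calls and gained 64.

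The rDNA repeat was examined because BAZ2A acts there. BRD2 in MDA-MB-231 was concentrated over the transcribed part, with 40.5 RPM per bin over the first 13 kb and 3.56 over the spacer with DMSO. The coding part fell to 39.3 with GSK2801 (ratio 0.97), 37.7 with JQ1 (0.93, interval 0.92 to 0.94) and 31.0 with both (0.77, 0.76 to 0.77). The 5′ external transcribed spacer, at the start of the 47S precursor, fell most with both drugs, from 49.95 to 34.3 (ratio 0.69, 0.67 to 0.70), and 18S and 28S each had a ratio of 0.81. All 52 coding bins were lower with both drugs. The bin with the highest value, at 1251 to 1500, went from 89.0 to 62.0. Spacer values rose to 3.76, 5.19 (ratio 1.46, 1.43 to 1.49) and 7.52 (2.11, 2.07 to 2.15), so the coding to spacer ratio went from 11.4 to 10.5, 7.26 and 4.12. The intervals cover counting error only. The log2 changes of the coding part were -0.04 with GSK2801 and -0.1 with JQ1. In promoter scores the DMSO and NT siRNA controls differed by a median of 0.29. A less enriched library and a real shift of BRD2 from the coding part to the spacer cannot be told apart with 1 library per group.

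BRD4 showed no such concentration on the rDNA. With DMSO the coding part held 2.79 RPM per bin and the spacer 2.24, and the highest bin lay at 37001 to 37250 with 17.4 RPM. With JQ1 the coding part stood at 5.75 (ratio 2.06, 1.97 to 2.15) and the spacer at 3.71 (1.66, 1.6 to 1.72). With both drugs they stood at 7.24 (2.59, 2.5 to 2.69) and 5.70 (2.55, 2.48 to 2.62). The coding to spacer ratio was 1.25 with DMSO, 1.41 with GSK2801, 1.55 with JQ1 and 1.27 with both. As shares of each library's total over the repeat, the spacer ratios with JQ1 and with both drugs lay below 0 on the log2 scale. These BRD4 libraries held 36.2, 43.0, 9.8 and 17.3 M reads. With 1 library per group, a larger share of unspecific reads and a gain of BRD4 on the repeat cannot be told apart.

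**Figure D3:**
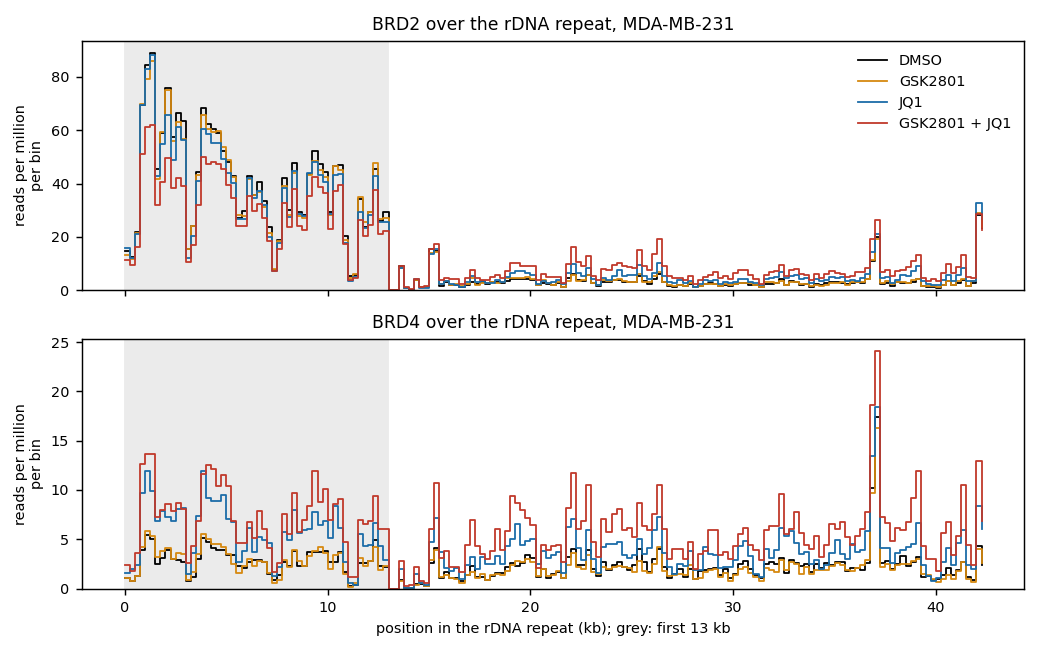
RPM per bin of 250 bp against position in the rDNA repeat (kb) for BRD2 (top) and BRD4 (bottom) in MDA-MB-231, 1 line per library, with the first 13 kb in grey. The BRD2 line with both drugs lies below DMSO over the grey part (31.0 against 40.5 on average) and above it over the spacer (7.52 against 3.56).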

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

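Differences between cell lines, antibodies and libraries stood out below, and none of them was tested, since each group held 1 library. The check of distal regions for BAZ2B siRNA with JQ1 was chosen only after the result was seen, and the others were set beforehand.

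Promoters and enhancers ranked differently between MDA-MB-231 and HCC1806. The promoter median minus the enhancer median of BRD2 with JQ1 was 0.34 in the drug experiment and 0.43 in the siRNA experiment of MDA-MB-231, 0.00 in SUM159 and -0.25 in HCC1806. With no pseudocount SUM159 ranked as MDA-MB-231 did, with promoters at -0.63 and enhancers at -0.78, and HCC1806 kept its order, with -0.98 and -0.71. With BAZ2B siRNA and JQ1 it was 0.30 in MDA-MB-231 and -0.37 in HCC1806. A candidate explanation is that the HCC1806 table holds values without background subtraction, which would flatten weak enhancers. Peak calls do not depend on those values. Among control peaks of matched strength, the share retained with JQ1 in HCC1806 was 7.5 points lower in enhancers than in promoters (a difference of -7.5), the same direction as in both MDA-MB-231 experiments (-17.0 and -15.0) and SUM159 (-8.3). This meets what the explanation needs, though JQ1 was given at 500 nM in HCC1806 and 100 nM elsewhere. The line and the dose cannot be told apart from one another here, and a biological difference between the lines stays open and untested.

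Adding GSK2801 to JQ1 moved the antibodies in different directions. The median change against JQ1 was -0.37 for BRD2, -0.01 for BRD4 and 0.25 for BRD9 in MDA-MB-231, and -0.16 for BRD2 in SUM159. The difference was not tested, and no explanation was examined for it.

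BRD2 fell across most promoters with JQ1 in MDA-MB-231. If the JQ1 library were merely weaker by 1 factor at every promoter, gene-to-gene differences would be noise and would not recur in separate libraries. They recurred, with r of 0.80 over 5633 genes between the drug and siRNA experiments. A dependence on signal level and region width alone was also argued against, since r was 0.80 after removal of both trends. In the 441 genes with the highest values in both experiments, r was 0.85. A shared input subtraction in both tables stays open, as does a single factor added on top of the gene-specific changes, since the scaling of the scores is not stated. That the recurring part reflects displacement of BRD2 by JQ1 may be put forward only as a hypothesis.

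BAZ2B siRNA with JQ1 gave lower BRD2 than NT siRNA with JQ1 nearly everywhere in MDA-MB-231. An effect of BAZ2B siRNA on particular promoters that also occurs in HCC1806 was predicted to give a positive correlation between the lines. Their changes had r of -0.14 over 4787 genes. The HCC1806 changes had an SD across genes of only 0.14, and the lines differed in the unit of the values and the JQ1 dose. The low r therefore cannot exclude such an effect. Of 3600 distal regions 96.8% had a lower value too. A weaker library and a real loss of BRD2 at all regions both give this, so with 1 library per group they cannot be told apart. An effect of BAZ2B siRNA on particular promoters in MDA-MB-231 alone was not tested and stays open.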

How the results depend on the processing

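The width-matched random lists, the rDNA ratio to the spacer and the restriction to regions of up to 5 kb were chosen only after the results were seen. Where the text below gives no cause, the cause was not tested. A count is said to move when it changes by more than 1.5 times, or to or from 0. Among libraries of known depth, depth limits BRD4 with JQ1 most, at 9.8 M reads. This holds for its rDNA values and, if the samples of the same title are 1 library, for its peaks and promoter values.

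Setting the median change to 0 in each comparison moved 36 of 54 counts of lower and higher genes, because the library-wide shift was removed. Numbers are given as lower and higher, “over” means against that library, and siRNA names are shortened to NT, BAZ2A and BAZ2B. When centred, MDA-MB-231 BRD2 had 74 and 67 with JQ1, 187 and 151 with both drugs and 15 and 1 with both drugs over JQ1. When centred, MDA-MB-231 BRD4 had 0 and 0 with GSK2801, 210 and 143 with JQ1, 286 and 178 with both drugs and 3 and 1 with both drugs over JQ1. When centred, MDA-MB-231 BRD9 had 0 and 1 with GSK2801, 222 and 91 with JQ1, 181 and 115 with both drugs and 15 and 36 with both drugs over JQ1. When centred, SUM159 had 87 and 53 with JQ1, 140 and 126 with both drugs and 6 and 0 with both drugs over JQ1. When centred, MDA-MB-231 siRNA had 106 and 72 with NT + JQ1, 79 and 70 with BAZ2A + JQ1, 189 and 97 with BAZ2B + JQ1, 5 and 5 with BAZ2A + JQ1 over NT + JQ1 and 66 and 4 with BAZ2B + JQ1 over NT + JQ1. When centred, HCC1806 had 54 and 60 with NT + JQ1 and 71 and 66 with BAZ2B + JQ1.

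A pseudocount of 0.5 moved 7 counts. At 0.5, MDA-MB-231 BRD2 had 586 and 6 with JQ1 and 127 and 1 with both drugs over JQ1. At 0.5, MDA-MB-231 BRD4 had 3 and 2 with both drugs over JQ1. At 0.5, MDA-MB-231 BRD9 had 0 and 19 with GSK2801 and 13 and 217 with both drugs over JQ1. At 0.5, SUM159 had 0 and 3 with GSK2801.

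A pseudocount of 5 moved 33 counts, as it shrinks changes of low values by construction. At 5, MDA-MB-231 BRD2 had 98 and 1 with JQ1, 616 and 2 with both drugs and 1 and 0 with both drugs over JQ1. At 5, MDA-MB-231 BRD4 had 0 and 0 with GSK2801, 176 and 26 with JQ1, 236 and 36 with both drugs and 0 and 0 with both drugs over JQ1. At 5, MDA-MB-231 BRD9 had 0 and 0 with GSK2801, 257 and 0 with JQ1, 163 and 5 with both drugs and 0 and 0 with both drugs over JQ1. At 5, SUM159 had 334 and 2 with JQ1, 876 and 4 with both drugs and 2 and 0 with both drugs over JQ1. At 5, MDA-MB-231 siRNA had 0 and 0 with BAZ2A, 0 and 0 with BAZ2B, 145 and 3 with NT + JQ1, 230 and 2 with BAZ2A + JQ1, 2800 and 1 with BAZ2B + JQ1, 0 and 0 with BAZ2A + JQ1 over NT + JQ1 and 368 and 0 with BAZ2B + JQ1 over NT + JQ1. At 5, HCC1806 had 1118 and 1 with NT + JQ1 and 2346 and 0 with BAZ2B + JQ1.

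Without the filter on low values, which adds weakly bound genes by construction, 42 counts moved. Unfiltered, MDA-MB-231 BRD2 had 1 and 20 with GSK2801, 707 and 31 with JQ1, 2992 and 27 with both drugs and 155 and 2 with both drugs over JQ1. Unfiltered, MDA-MB-231 BRD4 had 2 and 28 with GSK2801, 497 and 299 with JQ1, 610 and 379 with both drugs and 24 and 43 with both drugs over JQ1. Unfiltered, MDA-MB-231 BRD9 had 1 and 35 with GSK2801, 882 and 46 with both drugs and 6 and 177 with both drugs over JQ1. Unfiltered, SUM159 had 3 and 38 with GSK2801, 1830 and 34 with JQ1, 3427 and 61 with both drugs and 36 and 25 with both drugs over JQ1. Unfiltered, MDA-MB-231 siRNA had 9 and 5 with BAZ2A, 1 and 15 with BAZ2B, 887 and 78 with NT + JQ1, 1662 and 13 with BAZ2A + JQ1, 8080 and 1 with BAZ2B + JQ1, 48 and 5 with BAZ2A + JQ1 over NT + JQ1 and 4209 and 0 with BAZ2B + JQ1 over NT + JQ1. Unfiltered, HCC1806 had 4156 and 3 with NT + JQ1 and 6851 and 1 with BAZ2B + JQ1.

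Keeping regions of up to 5 kb only, which leaves fewer genes, moved 37 counts. Up to 5 kb, MDA-MB-231 BRD2 had 190 and 2 with JQ1, 976 and 3 with both drugs and 7 and 0 with both drugs over JQ1. Up to 5 kb, MDA-MB-231 BRD4 had 0 and 0 with GSK2801, 60 and 5 with JQ1, 70 and 6 with both drugs and 0 and 0 with both drugs over JQ1. Up to 5 kb, MDA-MB-231 BRD9 had 0 and 0 with GSK2801, 171 and 1 with JQ1, 78 and 2 with both drugs and 0 and 2 with both drugs over JQ1. Up to 5 kb, SUM159 had 0 and 0 with GSK2801, 336 and 1 with JQ1, 722 and 1 with both drugs and 0 and 0 with both drugs over JQ1. Up to 5 kb, MDA-MB-231 siRNA had 0 and 0 with BAZ2A, 0 and 0 with BAZ2B, 234 and 4 with NT + JQ1, 456 and 1 with BAZ2A + JQ1, 2357 and 1 with BAZ2B + JQ1, 0 and 0 with BAZ2A + JQ1 over NT + JQ1 and 737 and 0 with BAZ2B + JQ1 over NT + JQ1. Up to 5 kb, HCC1806 had 1595 and 0 with NT + JQ1, 2243 and 0 with BAZ2B + JQ1 and 0 and 0 with BAZ2B + JQ1 over NT + JQ1.

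A 1.5-fold rule, which admits smaller changes by construction, moved 47 counts. By 1.5-fold, MDA-MB-231 BRD2 had 0 and 48 with GSK2801, 2246 and 57 with JQ1, 4343 and 28 with both drugs and 1026 and 1 with both drugs over JQ1. By 1.5-fold, MDA-MB-231 BRD4 had 0 and 74 with GSK2801, 1244 and 364 with JQ1, 1370 and 446 with both drugs and 87 and 47 with both drugs over JQ1. By 1.5-fold, MDA-MB-231 BRD9 had 0 and 307 with GSK2801, 3864 and 35 with JQ1, 2356 and 91 with both drugs and 25 and 698 with both drugs over JQ1. By 1.5-fold, SUM159 had 0 and 28 with GSK2801, 3620 and 16 with JQ1, 4516 and 25 with both drugs and 118 and 4 with both drugs over JQ1. By 1.5-fold, MDA-MB-231 siRNA had 38 and 18 with BAZ2A, 10 and 27 with BAZ2B, 2121 and 68 with NT + JQ1, 3502 and 17 with BAZ2A + JQ1, 6021 and 2 with BAZ2B + JQ1, 144 and 11 with BAZ2A + JQ1 over NT + JQ1 and 5805 and 1 with BAZ2B + JQ1 over NT + JQ1. By 1.5-fold, HCC1806 had 1 and 1 with BAZ2B, 5270 and 12 with NT + JQ1, 5880 and 1 with BAZ2B + JQ1 and 23 and 0 with BAZ2B + JQ1 over NT + JQ1.

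Requiring −log10 q of at least 10 lowered the number of peaks in all 26 libraries, by construction. Strict lists of MDA-MB-231 BRD2 held 12932 with DMSO, 14918 with GSK2801, 11130 with JQ1 and 7968 with both drugs. Strict lists of MDA-MB-231 BRD4 held 26384 with DMSO, 30881 with GSK2801, 14125 with JQ1 and 23689 with both drugs. Strict lists of MDA-MB-231 BRD9 held 13054 with DMSO, 21657 with GSK2801, 3411 with JQ1 and 7077 with both drugs. Strict lists of SUM159 held 20234 with DMSO, 26585 with GSK2801, 13431 with JQ1 and 13892 with both drugs. Strict lists of MDA-MB-231 siRNA held 16025 with NT, 15707 with BAZ2A, 17076 with BAZ2B, 13909 with NT + JQ1, 10925 with BAZ2A + JQ1 and 6602 with BAZ2B + JQ1. Strict lists of HCC1806 held 20181 with NT, 20272 with BAZ2B, 11143 with NT + JQ1 and 10720 with BAZ2B + JQ1.

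With the same strict peaks, 26 of 40 numbers of promoter calls lost and gained moved by over 1.5 times. Lost and gained, MDA-MB-231 BRD2 had 189 and 770 with GSK2801, 1008 and 615 with JQ1 and 2448 and 348 with both drugs. Lost and gained, MDA-MB-231 BRD4 had 170 and 862 with GSK2801, 3454 and 161 with JQ1 and 1357 and 652 with both drugs. Lost and gained, MDA-MB-231 BRD9 had 220 and 2520 with GSK2801. Lost and gained, SUM159 had 1053 and 108 with both drugs. Lost and gained, MDA-MB-231 siRNA had 324 and 374 with BAZ2A, 276 and 418 with BAZ2B, 735 and 557 with NT + JQ1, 1293 and 271 with BAZ2A + JQ1 and 4053 and 65 with BAZ2B + JQ1. Lost and gained, HCC1806 had 2244 and 45 with NT + JQ1 and 2487 and 34 with BAZ2B + JQ1. With 50% of the peak inside the promoter region, or 2.5 kb on each side of the start site, all 40 stayed within 1.5 times.

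Requiring 50% of the control peak to be overlapped moved all 34 shares, down by construction. By 50%, MDA-MB-231 BRD2 kept 85.3% with GSK2801, 53.7% with JQ1 and 36.0% with both drugs. By 50%, MDA-MB-231 BRD4 kept 87.9% with GSK2801, 41.4% with JQ1 and 59.3% with both drugs. By 50%, MDA-MB-231 BRD9 kept 89.8% with GSK2801, 28.7% with JQ1 and 46.0% with both drugs. By 50%, SUM159 kept 85.5% with GSK2801, 37.0% with JQ1 and 36.7% with both drugs. By 50%, MDA-MB-231 siRNA kept 73.5% with BAZ2A, 80.5% with BAZ2B, 52.1% with NT + JQ1, 40.5% with BAZ2A + JQ1 and 16.3% with BAZ2B + JQ1. By 50%, HCC1806 kept 77.2% with BAZ2B, 27.5% with NT + JQ1 and 23.6% with BAZ2B + JQ1. By 50%, the controls shared 44.7% of HCC1806 in NT, 49.9% of HCC1806 in SUM159, 82.7% of BRD2 in NT, 91.3% of BRD2 in BRD4, 57.4% of BRD2 in BRD9, 69.5% of BRD2 in SUM159 and 56.4% of NT in HCC1806. By 50%, they also shared 61.7% of NT in BRD2, 33.5% of BRD4 in BRD2, 39.3% of BRD4 in BRD9, 52.0% of BRD9 in BRD2, 90.3% of BRD9 in BRD4, 43.1% of SUM159 in HCC1806 and 35.7% of SUM159 in BRD2. Here BRD2, BRD4, BRD9 and NT name control libraries of MDA-MB-231, and SUM159 and HCC1806 those of the other lines.

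Counting only control peaks with −log10 q of at least 10, which are the strongest, raised all 34 shares. Among strict peaks, MDA-MB-231 BRD2 kept 99.8% with GSK2801, 93.2% with JQ1 and 83.4% with both drugs. Among strict peaks, MDA-MB-231 BRD4 kept 99.8% with GSK2801, 86.7% with JQ1 and 92.9% with both drugs. Among strict peaks, MDA-MB-231 BRD9 kept 100.0% with GSK2801, 70.2% with JQ1 and 84.5% with both drugs. Among strict peaks, SUM159 kept 99.8% with GSK2801, 83.9% with JQ1 and 83.5% with both drugs. Among strict peaks, MDA-MB-231 siRNA kept 98.7% with BAZ2A, 99.3% with BAZ2B, 91.4% with NT + JQ1, 83.4% with BAZ2A + JQ1 and 63.8% with BAZ2B + JQ1. Among strict peaks, HCC1806 kept 99.3% with BAZ2B, 75.0% with NT + JQ1 and 71.3% with BAZ2B + JQ1. Among strict peaks, the controls shared 74.2% of HCC1806 in NT, 77.4% of HCC1806 in SUM159, 99.1% of BRD2 in NT, 99.3% of BRD2 in BRD4, 87.7% of BRD2 in BRD9, 91.2% of BRD2 in SUM159 and 85.0% of NT in HCC1806. Among strict peaks, they also shared 94.7% of NT in BRD2, 67.3% of BRD4 in BRD2, 89.0% of BRD4 in BRD9, 75.9% of BRD9 in BRD2, 99.2% of BRD9 in BRD4, 76.4% of SUM159 in HCC1806 and 72.5% of SUM159 in BRD2.

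Taking the same number of strongest peaks from each library moved all 34 shares, for a reason not tested. With equal numbers, MDA-MB-231 BRD2 kept 86.6% with GSK2801, 75.4% with JQ1 and 70.2% with both drugs. With equal numbers, MDA-MB-231 BRD4 kept 87.7% with GSK2801, 70.6% with JQ1 and 71.7% with both drugs. With equal numbers, MDA-MB-231 BRD9 kept 80% with GSK2801, 60.8% with JQ1 and 61.0% with both drugs. With equal numbers, SUM159 kept 83.8% with GSK2801, 69.9% with JQ1 and 67.1% with both drugs. With equal numbers, MDA-MB-231 siRNA kept 87.9% with BAZ2A, 88.4% with BAZ2B, 77.7% with NT + JQ1, 78.3% with BAZ2A + JQ1 and 73.5% with BAZ2B + JQ1. With equal numbers, HCC1806 kept 90.0% with BAZ2B, 72.9% with NT + JQ1 and 71.1% with BAZ2B + JQ1. With equal numbers, the controls shared 58.5% of HCC1806 in NT, 54.7% of HCC1806 in SUM159, 81.8% of BRD2 in NT, 77.0% of BRD2 in BRD4, 62.4% of BRD2 in BRD9, 66.5% of BRD2 in SUM159 and 60.5% of NT in HCC1806. With equal numbers, they also shared 78.1% of NT in BRD2, 66.9% of BRD4 in BRD2, 74.0% of BRD4 in BRD9, 63.9% of BRD9 in BRD2, 85.9% of BRD9 in BRD4, 53.3% of SUM159 in HCC1806 and 61.5% of SUM159 in BRD2.

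The median departure from the sum moved with the pseudocount, by construction, and stayed below 0 or at 0.00. At 0.5 it was -0.56 in MDA-MB-231 BRD2, -0.18 in BRD4, 0.00 in BRD9, -0.31 in SUM159, -0.20 for BAZ2A, -1.03 for BAZ2B and -0.29 in HCC1806. At 5 it was -0.37, -0.13, -0.04, -0.24, -0.14, -0.65 and -0.22 in that order. The correlation of the JQ1 changes in MDA-MB-231 was 0.77 without the filter, and 83.25% of genes then had the same sign, down from 89.95%.

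The number of lists outside the random range moved, by that rule, in 13 cases, and changed by less in others, such as from 5 to 7 with the mean for MDA-MB-231 BRD2 with both drugs over JQ1. With the mean over members there were 4 with BAZ2A siRNA, 1 with BAZ2B siRNA and 1 with BAZ2B siRNA + JQ1 over NT + JQ1 in MDA-MB-231, 3 for BRD4 with GSK2801 and 0 with BAZ2B siRNA in HCC1806. Against width-matched lists there were 4 with BAZ2B siRNA + JQ1 over NT + JQ1, 0 with BAZ2B siRNA and 1 with NT + JQ1 in HCC1806, 2 for BRD4 with GSK2801 and 1 for BRD9 with JQ1. Against unmatched lists there were 1 with BAZ2B siRNA + JQ1 over NT + JQ1 in HCC1806, 0 for BRD9 with both drugs over JQ1 and 1 for BRD9 with JQ1. Across all list results, the mean took 15 back inside the range and put 23 outside it, width matching 10 and 8, and no matching 6 and 6. None reversed.

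On the rDNA, the ratio to the spacer of the same library gave the coding part of BRD2 a log2 change of -0.12 with GSK2801, -0.65 with JQ1 and -1.46 with both drugs, because the spacer rose. For BRD4 it gave 0.18, 0.31 and 0.02. As a share of the repeat's total, the coding part of BRD2 changed by -0.02, -0.13 and -0.36 and that of BRD4 by 0.11, 0.19 and 0.01. The spacer of BRD4 changed by -0.07 with GSK2801 and reversed to -0.12 with JQ1 and -0.01 with both drugs, since the whole repeat rose together. With 1 kb bins the spacer of BRD2 stood at 0.51 with JQ1 and 0.99 with both drugs. Without the highest bin the spacer of BRD4 stood at 1.4 with both drugs.

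Among named genes, centring reversed 14 called falls, because the median itself was lower. With BAZ2B siRNA and JQ1 in HCC1806 these were CDK6 (0.03), CEBPB (0.01), FOSL1 (0.03), GATA3 (0.06), HEXIM1 (0.07) and MYC (0.08). In MDA-MB-231 they were ATR (0.31), BAZ2A (0.12), BCL2L1 (0.16), CCND1 (0.01), CDK1 (0.22), NT5E (0.10), POLR1A (0.00) and SERPINE1 (0.34). Centring also took 198 named changes below 2-fold and put 56 above it, and left 1444 as they were. A pseudocount of 5 took 149 below 2-fold, and one of 0.5 put 31 above it. No named change reversed with either pseudocount.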

Other observations

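The comparison of summed values below was chosen only after the medians were seen, and the comparison of medians was set beforehand.

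Introns lost more BRD2 than promoters with JQ1 in MDA-MB-231. The 280 intronic regions of the drug experiment had a median of -0.83 with JQ1 and -1.20 with both drugs, and the 397 of the siRNA experiment -0.96 with NT siRNA and JQ1. In SUM159 the 785 intronic regions had a median of -0.49 and in HCC1806 the 336 intronic regions -0.57. GSK2801 by itself came with more peaks than DMSO in all 4 drug experiments, and in BRD9 with 1164 gained promoter calls against 127 lost. Interferon response genes had a median of -0.80 over 6 genes with BAZ2B siRNA and JQ1 in HCC1806 (percentile 95.02), within the random range. The apoptosis list in HCC1806 with NT siRNA and JQ1 stood at -0.70 over 16 genes (97.29), just within it.

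Wide distal regions, which resemble super-enhancers, may lose more BRD2 with JQ1 than narrow ones. In 4 of 4 comparisons the median of regions wider than 10 kb lay below that of narrower regions matched on value per kb, by -0.33 and -0.30 in MDA-MB-231, -0.36 in SUM159 and -0.06 in HCC1806. Because a wide region has a higher value, the pseudocount shrinks its change less. The ratio of summed values, which hardly feels the pseudocount, differed by 0.03, -0.04, -0.57 and -0.14 in the same order. Only 2 of the 4 comparisons, SUM159 and HCC1806, were lower in sums by more than 0.1, so the hypothesis is left undecided.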
